A study of Mus musculus with 3 samples.

How the data were processed

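DNase I cuts accessible chromatin more often than packed chromatin, and the ends of the resulting fragments were sequenced and placed on the mouse genome build mm10. The series holds 3 libraries of R1, a mouse embryonic stem cell line, in 1 group. Libraries with the technical replicate numbers 1 and 3 belong to biological replicate 1, and the remaining library is biological replicate 2. The file lists of both libraries of biological replicate 1 name the series-level files, which are taken here as pooled over them, and biological replicate 2 has files of its own. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here.

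The authors made 4 kinds of peak or region list for each biological replicate from 2 alignments. The main list holds peaks of varying width whose signal is a peak height, in a unit that the authors scaled for depth. Below 200 cuts, 100% of the heights lay within 0.02 of a whole multiple of a single step per library, so that 1 step is 1 cut. If the scale is per 1000000 cuts (M), which the files do not state, the steps give 322 M cuts for biological replicate 1 and 41.7 M for biological replicate 2. The ratio of the depths is 7.74. A stricter list of the same kind was deposited beside it. The best FDR inside each peak reached at most 0.0499 in the main lists of both replicates and at most 0.000998 and 0.000999 in the stricter lists. In the deposited lists of peaks 150 bp wide, the height is a whole-number count that is not scaled for depth. The deposited hotspots, which are broad regions of enriched cutting, carry the −log10 of the best FDR in the region, limited to 100. The authors also gave a p-value-like measure per base, the FDR of the local cut rate, listed up to 0.05. Each deposited footprint, a short stretch protected from cutting inside an accessible region, carries the same FDR of 0.01, so footprints could not be ranked. The height of a peak is the authors' own value and was used here to describe, rank and select peaks within a list. Heights of the replicates are printed side by side but no ratio of them is read as a difference in accessibility. Peaks of a list can overlap each other. The FDR values per base came from 1 table per replicate, and tables of any other alignment were not used here.

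Genes came from the mm10 annotation, with 55413 genes, of which 21938 are protein-coding with 93513 transcript starts. A promoter peak is a peak that overlaps the 500 bp on either side of any annotated transcription start site (TSS) of the gene. A distal peak is more than 1 kb from every TSS. A promoter was called CpG-rich when the 1 kb around the 5′-most TSS of the gene had an observed over expected CpG ratio of at least 0.6 and a GC content of at least 50%. The promoter peak of the same gene can lie at another TSS. Coordinates are 1-based. Peak classes were assigned by peak centre in the order promoter, exon, intron and intergenic.

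Overlap of the lists was counted from 1 bp in both directions, beside 100 shuffles of the same peaks within their chromosomes. The genomic distribution was compared with 10 shuffles. Agreement of heights was given as Spearman and Pearson correlation across overlapped peaks, which are not independent replicates. With 1 group and 2 biological replicates no test across samples exists. The members of 18 gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method over the lists. The units of these tests are genes, and neighbouring genes are not independent. Distal peaks within 50 kb were counted per gene, and the median of each list was placed among 10000 random lists of the same size with the same number of promoter peaks, with the central 95% as the range of chance and no adjustment over the lists. Matches to 20 consensus motifs were counted in peaks and in equally wide windows 2 kb to either side that overlap no peak, and in footprints and equally wide windows elsewhere in the same peaks, with two-sided Fisher's exact tests adjusted over the motifs. Footprint lists were compared with each other beside 100 draws in which each footprint was moved at random inside its peak. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

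The gene lists were core pluripotency, primed pluripotency, housekeeping, neural ectoderm, mesoderm, endoderm, trophoblast, germ cell, 2-cell-like, fibroblast (feeder cells), blood, adult tissue, chromatin regulators, cell cycle, signalling, imprinted, Hox and olfactory receptor genes. Named genes were chosen by a rule: per list, the 3 members with the highest promoter peak in biological replicate 1 that also had one in biological replicate 2, then the first 2 members in alphabetical order with no promoter peak in either, and Pou5f1, Sox2, Nanog, Klf4 and Esrrb always. Not every gene that the rule names is described here. The rule also names the 5 peaks highest in biological replicate 1 that overlap a peak of biological replicate 2, and the 10 genes with the most distal peaks. The lists, the motifs, the tests, this rule and the alternatives were chosen before the data were examined, except for a control in which each consensus was written backwards, the comparison of chromosomes and the tests of the closing section, which were chosen afterwards. The alternatives were a reciprocal overlap of 50%, the stronger 50% of each list, equal numbers of peaks, the other deposited lists, promoters of 1 kb, the 5′-most TSS alone, biological replicate 2 alone, comparison within the promoter's CpG class, distal windows of 20 kb and 100 kb, motif windows 10 kb away, and distal peaks alone.

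The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and pyfaidx 0.9.0.4, with figures drawn by matplotlib 3.10.9, and samtools 1.23.1 and bedtools 2.31.1. The procedures were tested on simulated data. Overlap counts on 20000 simulated peaks were the same as those of bedtools. Of 100 simulated lists of 15 genes with a strongly lowered share of promoter peaks, the Fisher exact test found 89, and it called 4 of 100 unchanged lists. For lists of 30 genes the numbers were 97 and 1. No raised share was simulated, so these numbers do not give the power to find lists above other genes. All 20 motifs were recovered after planting.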

Results

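DNase-seq was carried out on R1, a line of mouse embryonic stem (ES) cells, which are taken from the early embryo and can give rise to all tissues of the body. The 3 libraries form 1 group and stand for 2 biological replicates, biological replicate 1 with 2 libraries, whose files are taken here as pooled, and biological replicate 2 with 1 library. Depth differed widely between them. If peak heights are scaled per 1000000 cuts (M), which the files do not state, the steps between heights give 322 M cuts for replicate 1 and 41.7 M for replicate 2. Replicate 1 had 307373 peaks of median width 200 bp, covering 62.7 Mb or 2.37% of the sequenced genome, and replicate 2 had 94328 peaks of median width 180 bp, covering 17.2 Mb or 0.648%. The median peak height amounted to 116 cuts in replicate 1 and 42.0 in replicate 2. Replicate 1 is the reference in what follows because it is the deeper data set. No condition was varied, so the comparisons are between the replicates, between gene groups and between kinds of sequence. The labels state no aim beyond the assay and the cell line.

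Of the 5 peaks highest in replicate 1 that a replicate 2 peak overlapped, 3 lay at promoters, those of Sp1, Rnf5 and Aars. Heights in replicate 2 played no part in this ranking. The highest of the 5 covered chr13:66711141–66711300 (mm10), an intergenic site 191565 bp from the nearest protein-coding TSS, that of Uqcrb, with a height of 35.3 in replicate 1 and 22.5 in replicate 2. The next lay 42 bp from a TSS of Sp1, which encodes a transcription factor that binds GC-rich promoters (chr15:102405981–102406220, height 31.5). Further ones were at promoters of Rnf5, a ubiquitin ligase gene (chr17:34603661–34603960, height 31.5), and Aars, which encodes the alanyl-tRNA synthetase (chr8:111033701–111033860, height 29.7). The remaining one lay in an intron near the zinc finger gene Zfp978 (chr4:147417441–147417720, height 30.98 in replicate 1 and 9.32 in replicate 2). For the Uqcrb and Zfp978 sites, 33.1% and 40.8% of the 31-base words of the sequence occurred elsewhere in mm10, against 0 at the Sp1, Rnf5 and Aars promoters.

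Nearly all replicate 2 peaks were found again in replicate 1, and most replicate 1 peaks were not found in replicate 2. Of the replicate 2 peaks, 94.6% (95% interval 94.5 to 94.8) were overlapped by a replicate 1 peak, against 4.63% after shuffling, and 5055 were not. Of the replicate 1 peaks, 29.04% (28.9 to 29.2) were overlapped by a replicate 2 peak, against 1.44% after shuffling. The share rose with height, from 2.41% in the lowest 10% of replicate 1 peaks to 95.5% in the highest 10%. The median height in the lowest 10% amounted to 33 cuts, for which the lower depth of replicate 2 gives 4.26. With the same number of strongest peaks from each list the shares were 71.6% and 71.8%, and with a reciprocal overlap of 50% they were 23.9% for replicate 1 and 77.8% for replicate 2. Across the 89273 overlapped peaks, heights had a Spearman rho of 0.907 and a Pearson r of 0.912 on the log2 scale, a correlation across peaks and not across samples.

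**Figure D1:**
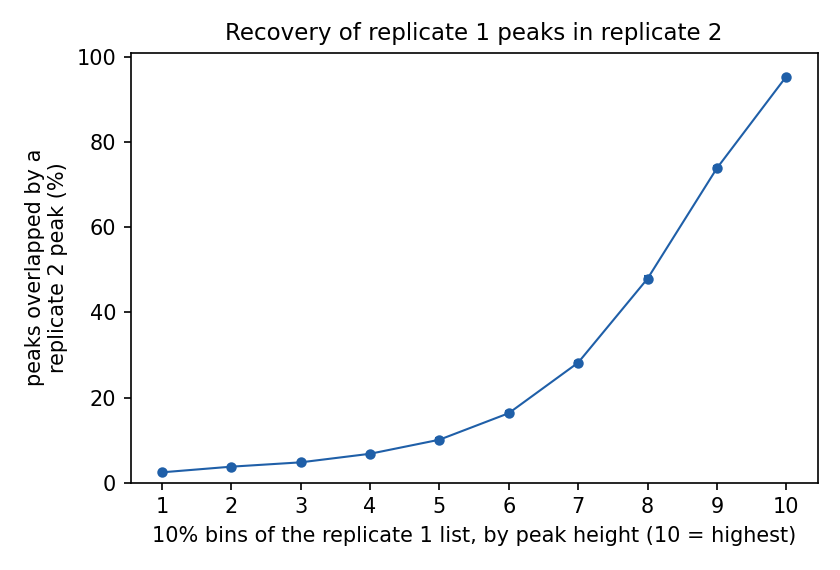
Share of replicate 1 peaks overlapped by a replicate 2 peak (vertical axis, %), for each 10% of the replicate 1 list ordered by peak height (horizontal axis), with exact 95% intervals that are smaller than the points in most places. The share climbs from 2.41% to 95.5%.

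Promoters held more peaks than chance places there in both replicates. The promoter class took 13.5% of peaks in replicate 1 and 23.4% in replicate 2, against 3.39% and 3.40% after shuffling. Exons took 6.35% and 4.53% (shuffled 3.86% and 3.87%), introns 40.0% and 34.8% (41.6% and 41.8%), and intergenic sequence 40.1% and 37.2% (51.2% and 50.97%). Over the replicates the promoter share was 18.5% ± 7.06 (SD, n = 2), the exon share 5.44% ± 1.29, the intron share 37.4% ± 3.69 and the intergenic share 38.7% ± 2.08. Promoter peaks were also the tallest class, with a median height of 0.862 in replicate 1 against 0.341 in introns and 0.307 in intergenic sequence. Bases with a cut-rate FDR up to 0.05 made up 4.08% of the sequenced genome in replicate 1 and 1.02% in replicate 2.

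A promoter peak was present at 16198 of 21938 protein-coding genes (73.8%) in replicate 1 and at 13376 (61.0%) in replicate 2. Both replicates had a peak at 13357 of these genes, neither had one at 5721, and 19 had one in replicate 2 alone. Genes with a CpG-rich promoter, judged at the 5′-most TSS, had a peak at any TSS in 99.3% of cases in replicate 1 and 90.9% in replicate 2. Genes with other promoters had one in 53.5% and 37.0%. Of the 18 gene lists, 8 had a higher share of genes with a promoter peak than other protein-coding genes in replicate 1, 2 had a lower share and 8 did not pass the test.

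Genes of the core pluripotency network, which keep ES cells undifferentiated, were almost all open at the promoter. Of 30 members, 29 had a promoter peak in replicate 1 (odds ratio 10.3, adjusted Fisher exact p = 0.00963) and 27 in replicate 2. With the 5′-most TSS alone, 24 had a promoter peak in replicate 1 and the call ended (adjusted Fisher exact p = 0.388). Fbxo15, a target of Oct4 and Sox2, had the highest (14.3), then Zfp42, the gene of the ES cell marker Rex1 (13.9), and Tbx3, a T-box factor that favours self-renewal (13.3). Dppa3, also called Stella, had no peak within 500 bp of a TSS in either replicate, though all 30 members had one within 1 kb in replicate 1, and had 45 distal peaks within 50 kb in replicate 1. Heights at the promoters of the 5 genes chosen in advance were 5.57 in replicate 1 and 3.15 in replicate 2 for Pou5f1, which encodes Oct4, 5.12 and 4.32 for Sox2, 3.85 and 2.06 for Nanog, 3.30 and 2.38 for Klf4, and 6.87 and 3.51 for Esrrb, which encodes an orphan nuclear receptor. All 10 primed pluripotency genes had a promoter peak in replicate 1, which did not pass the test in so short a list (adjusted Fisher exact p = 0.119), with Foxd3 (3.05), Lef1 (2.94) and Nodal (2.94) the highest.

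Genes of general cell functions, and imprinted genes, were open throughout in replicate 1. All 26 housekeeping genes had a promoter peak (adjusted Fisher exact p = 0.00316), with Vps29 of the retromer (14.99), Vcp, an ATPase of protein turnover (14.5), and Rplp0, a ribosomal protein gene (14.3), highest. All 23 chromatin regulators had one (adjusted Fisher exact p = 0.00629), led by Jarid2 of Polycomb complex PRC2 (14.9), the cohesin gene Rad21 (11.98) and Uhrf1, needed for maintenance DNA methylation (9.63). All 15 cell cycle genes had one (adjusted Fisher exact p = 0.0327), led by the replication genes Mcm3 (13.4), Mcm5 (12.02) and Pcna (8.88). All of these were also open in replicate 2. All 19 signalling genes had one (adjusted Fisher exact p = 0.0167), led by the ERK pathway feedback genes Dusp6 (13.8) and Spry4 (12.3) and by Stat3, which carries the LIF signal (10.5), and 16 had one in replicate 2. All 13 imprinted genes had one (adjusted Fisher exact p = 0.0485), among them Kcnq1ot1 (9.46), Peg3 (4.88) and Nnat (2.52), and 11 had one in replicate 2. The imprinted list is not all protein-coding, Kcnq1ot1 being an antisense transcript, yet it was compared with protein-coding genes only.

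Many Hox, neural ectoderm and mesoderm genes had a promoter peak in replicate 1 and none in replicate 2. All 39 Hox genes, which set position along the body axis, had one in replicate 1 (adjusted Fisher exact p = 9.60e-05), with a median height of 1.02 against 3.32 over all protein-coding genes with a promoter peak. The promoter peak of Hoxc13 was high at 17.8, and that of Hoxa5 was 3.93. In replicate 2 only 12 of the 39 had a promoter peak, so that Hox genes lay below other genes (30.8%, adjusted Fisher exact p = 0.000884). All 18 neural ectoderm genes had one in replicate 1 (adjusted Fisher exact p = 0.0167) and 10 in replicate 2 (55.6%, adjusted Fisher exact p = 0.716), with Gbx2 (6.39), Nes (3.92) and Lhx2 (3.59) highest. Among mesoderm genes the numbers were 15 of 18 in replicate 1 (adjusted Fisher exact p = 0.489) and 4 in replicate 2, below other genes there (22.2%, adjusted Fisher exact p = 0.00245). Runx1 (3.53), Kdr (3.35) and Mixl1 (1.02) were among those 4, and Meox1 and Myf5 had no promoter peak in either replicate.

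The remaining lineage lists did not pass the test in replicate 1. Endoderm genes had a promoter peak in 11 of 13 cases, with Cxcr4 (2.34), Gata6 (1.898) and Sox17 (1.84) open in both replicates and the liver genes Alb and Ttr in neither. Trophoblast genes also had 11 of 13, with Ascl2 (2.86), Tfap2c (2.43) and Gata3 (1.81) in both and the placental genes Prl3d1 and Tpbpa in neither. Germ cell genes had 12 of 13, with Piwil2 (3.63), Dazl (2.96) and Mael (2.10) highest and Acr, a sperm protease gene, in neither. Genes of the 2-cell-like state had 5 of 9, with Duxf3 (2.30) open in both replicates and Tcstv1 and Tdpoz4 in neither. Fibroblast genes, included because ES cells can be grown on feeder cells, had 17 of 19 with a median height of 0.437, and 7 in replicate 2. Fn1 (5.16), Snai2 (4.17) and Pdgfra (3.83) were the highest, and Acta2 and Col3a1, abundant in fibroblasts, had none. Blood genes had 6 of 12, with Lck (3.30) and Ikzf1 (1.80) open in both replicates and Cd4 in neither. In replicate 2, 2-cell-like genes (11.1%, adjusted Fisher exact p = 0.00632) and blood genes (25%, adjusted Fisher exact p = 0.0276) were below other genes, as they were in the stronger 50% of replicate 1 peaks (adjusted Fisher exact p = 0.00175 and 0.00484). Blood genes were also below them with the 5′-most TSS alone (adjusted Fisher exact p = 0.0319).

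Genes of adult organs and of smell were below other genes in replicate 1. Adult tissue genes had a promoter peak in 6 of 14 cases (42.9%, odds ratio 0.266, adjusted Fisher exact p = 0.0308), with Krt10 (2.58) and Ckm (2.55) open in both replicates and Aqp2 and Cyp2e1 in neither. Olfactory receptor genes had one in 84 of 1093 cases (7.69%, 95% interval 6.18 to 9.43) against 77.3% of other genes, and within the same CpG class of promoter the odds ratio was 0.0602 (stratified exact p = 1.06e-251). Olfr373 (1.64), Olfr156 (1.18) and Olfr464 (1.08) had the highest promoter peaks with a counterpart in replicate 2, and Olfr1 and Olfr10 had none. Compared only with promoters of the same CpG class, the calls ended for housekeeping, neural ectoderm, chromatin, cell cycle and adult tissue genes (adjusted stratified exact p from 0.0555 to 0.588). In that comparison fibroblast genes lay above other genes (adjusted stratified exact p = 0.0168). Without regard to CpG class, their share was under that of other genes in the stronger 50% of peaks (52.6% against 68.2%, adjusted Fisher exact p = 0.190). It was also under it in replicate 2 (36.8% against 61.0%, adjusted Fisher exact p = 0.0583), with no call in either setting. All housekeeping, neural ectoderm, chromatin and cell cycle genes had a peak, so their shares could not have been higher. Most of them had CpG-rich promoters, of which 99.3% carried a peak over all protein-coding genes. The comparison within the CpG class therefore had little or no room to show these lists above other genes. The core pluripotency call ended when the 5′-most TSS alone was used (80% of members, adjusted Fisher exact p = 0.388), as did those of signalling and imprinted genes. With promoters of 1 kb the calls of adult tissue, cell cycle and imprinted genes ended (adjusted Fisher exact p = 0.415, 0.0669 and 0.0953), and in replicate 2 alone those of signalling and imprinted genes did (0.0849 and 0.129). The imprinted call also ended in the stronger 50% of peaks (adjusted Fisher exact p = 0.103).

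**Figure D2:**
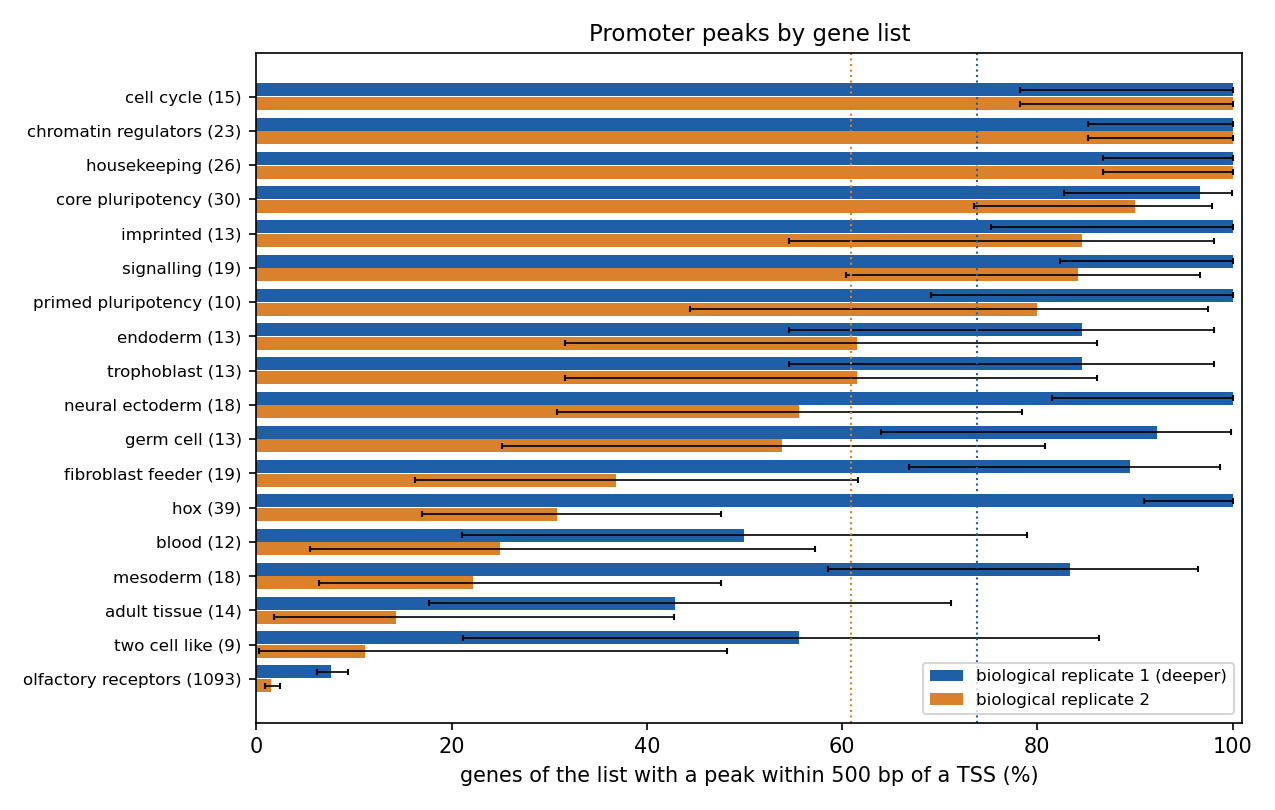
Share of genes in each list with a peak within 500 bp of a TSS (horizontal axis, %), in replicate 1 (blue) and replicate 2 (orange), with list sizes in brackets, exact 95% intervals as black lines and the share of other genes as dotted lines. Housekeeping, chromatin and cell cycle genes stay at 100% in both replicates, while Hox genes go from 100% in replicate 1 to 30.8% in replicate 2.

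Pluripotency genes were surrounded by more distal peaks than genes with a like promoter status. The median core pluripotency gene had 29 distal peaks within 50 kb, against 13 in random lists, above 100% of 10000 draws. Hox genes (27), signalling genes (24), chromatin regulators (22), trophoblast genes (22), primed pluripotency genes (21.5) and cell cycle genes (21) also lay above the central 95%, and olfactory receptor genes lay below it (4 against 7). Hox genes lie in clusters, so their windows share distal peaks, while the random lists drew genes independently. The range of chance is therefore too narrow for the Hox list. It would be so too for any other list with neighbouring members, the olfactory receptor list included, for which the sharing of windows was not examined. Imprinted genes (9 against 13, percentile 2.78) and fibroblast genes (10 against 13, percentile 8.29) lay low but inside the range. Housekeeping (15.5), neural ectoderm (15.5), mesoderm (14.5), endoderm (12), germ cell (11), adult tissue (10.5), blood (10.5) and 2-cell-like genes (7) were inside it too. In replicate 2, where the median gene had 3 distal peaks instead of 12, the core pluripotency (6 against 3), primed pluripotency (7 against 3), chromatin (6 against 3) and signalling lists (7 against 3) were still above the range, housekeeping genes were above it there (5 against 3), and the Hox, trophoblast and cell cycle lists were inside it at percentiles 68.5, 96.8 and 73.9. Within 100 kb in replicate 1, the primed pluripotency, trophoblast and cell cycle lists were inside it at percentiles 95.98, 95.2 and 93.4, housekeeping genes were above it (97.7) and fibroblast genes below it (1.46). Within 20 kb, neural ectoderm (9.5 against 5, percentile 99.9) and mesoderm genes (7.5 against 4.5, percentile 99.2) were above it, and the trophoblast (94.1) and cell cycle lists inside it. In the stronger 50% of peaks, fibroblast (3 against 7) and 2-cell-like genes (1 against 5) were below it and cell cycle genes inside it (95.4).

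The 10 genes with the most distal peaks in replicate 1 included groups of neighbours. Mkrn1, a ubiquitin ligase gene, had 87 within 50 kb in replicate 1, and its neighbours on chromosome 6, Rab19 and Slc37a3, had 61 and 60. On chromosome 14, Arhgef40 had 71, Ndrg2 69, Gm49342 64, Tppp2 63 and Pnp2 61. The others were Spry4 on chromosome 18 with 67 and Fam129a on chromosome 1 with 65. In replicate 2, Spry4 had 13 and Mkrn1 12, while Arhgef40 had 3, Ndrg2 and Tppp2 4, Fam129a 5 and the other 4 genes 6 or 7, against a median of 3. The counts of neighbouring genes share peaks and are not independent.

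At the core pluripotency genes the distal peaks included some of the tallest of the genome. Nanog (chr6:122707489–122714633, mm10, plus strand) had a peak 4.87 kb upstream of its 5′-most TSS, at chr6:122702521–122702720, with a height of 18.8 in replicate 1, taller than 99.9% of all peaks, and 9.82 in replicate 2. Downstream of Sox2 (chr3:34650405–34652461, plus strand) a group of peaks stood 106 to 111 kb from the TSS. The tallest of them, chr3:34761201–34761580, had a height of 15.3 in replicate 1, taller than 99.8% of peaks, and 8.55 in replicate 2, against 5.12 and 4.32 at the promoter of Sox2 itself. Upstream of Pou5f1 (chr17:35506018–35510772, plus strand), peaks lay at 1.05 kb (chr17:35504821–35505120, height 11.9) and 1.99 kb (chr17:35503921–35504140, height 10.1), both taller than the promoter peak. Only 50 kb to either side of the TSS was searched at the other 4 genes, against 150 kb at Sox2. In that window the tallest distal peaks of Klf4 (chr4:55527143–55532466, minus strand) and Esrrb (chr12:86361117–86521628, plus strand) lay 17.5 kb downstream of the Klf4 TSS (2.85) and 34.4 kb downstream of the 5′-most Esrrb TSS (2.31).

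**Figure D3:**
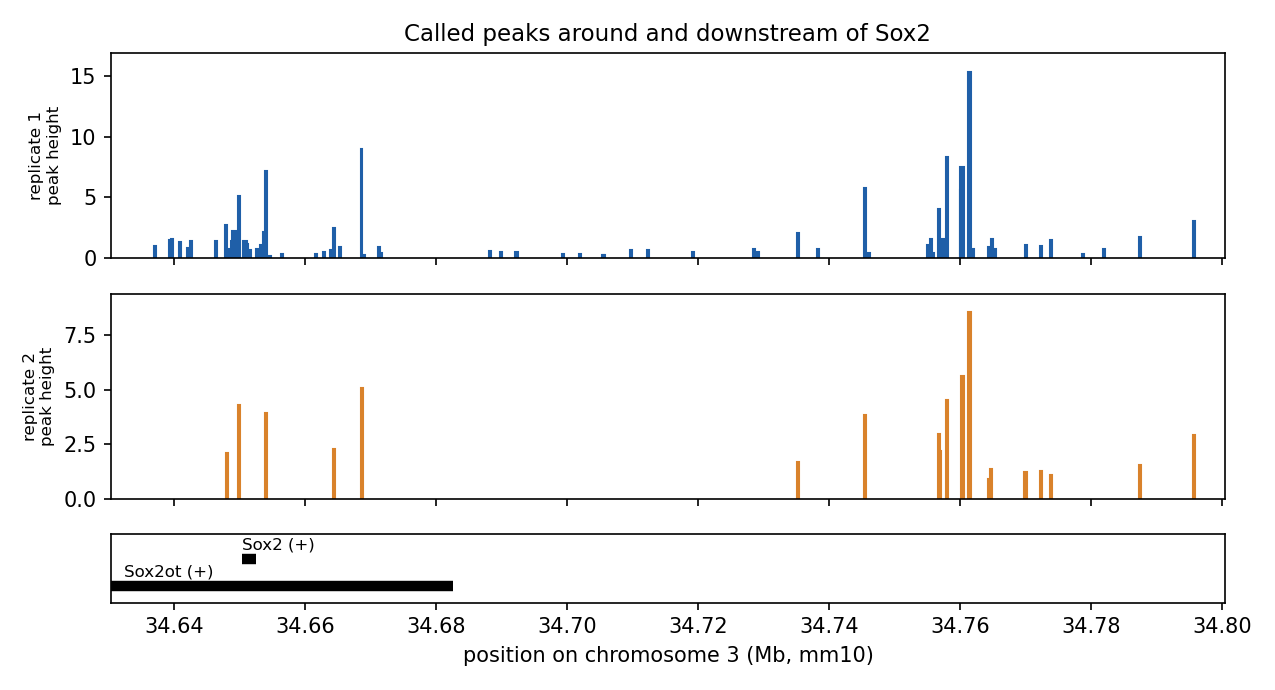
Peaks called over 170 kb around Sox2 on chromosome 3 (horizontal axis, Mb, mm10), drawn at their position with their deposited height (vertical axis, the authors' scale), 67 in replicate 1 (blue) and 19 in replicate 2 (orange), narrow peaks widened so that they can be seen, with Sox2 and its overlapping transcript Sox2ot below. The tallest bar in both replicates, 15.3 and 8.55, stands 111 kb downstream of the Sox2 TSS.

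Footprints, the short protected stretches that bound proteins can leave, were counted at the same loci. Within 50 kb of the 5′-most TSS, 175 footprints lay in peaks around Pou5f1, 123 around Nanog, 58 around Esrrb and 35 around Klf4, and 268 lay within 150 kb of Sox2. Of these, 18, 17, 2, 4 and 17 were also overlapped by a footprint of replicate 2, and no test against other loci was made. At the Pou5f1 promoter a footprint in both replicates held GGGCGGGGC, a KLF/SP match at chr17:35505987–35505995, 27 bp upstream of the TSS. In the peaks downstream of Sox2, 3 replicate 1 footprints held TGACCTTGA, the ESRRB consensus on the minus strand, at chr3:34756586–34756594, chr3:34757960–34757968 and chr3:34760574–34760582. Downstream of Nanog a footprint in both replicates held the CTCF match CCAGTAGGTGGC at chr6:122740136–122740147, and upstream of Esrrb a replicate 1 footprint held the RFX match GTTACCATGGTAAC at chr12:86360062–86360075.

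Footprint calls differed widely in number between the replicates. Replicate 1 had 897056 footprints of median width 10 bp, 82.2% centred in a peak, and replicate 2 had 97031 of median width 9 bp, 93.9% in a peak. A footprint was present in 78.5% of peaks in replicate 1 and in 47.3% in replicate 2, and 22.7% and 40.1% of footprints lay within 500 bp of a TSS. Of the replicate 2 footprints in peaks, 72.7% were overlapped by a replicate 1 footprint, against 50.1% when each was moved at random inside its peak. In the other direction 8.18% were overlapped, against 6.60% after moving.

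Of the 20 consensus sequences, those of REST, CTCF, RFX and NRF1 had the highest odds ratios in replicate 1 peaks. The consensus of REST, a repressor of neuronal genes, had an odds ratio of 115 in replicate 1 peaks against flanking windows (adjusted Fisher exact p = 3.49e-134). This value rests on 5 control windows with a match, and it was 297 with windows 10 kb away and 489 in the stronger 50% of peaks. In the genome 87.2% of the 376 REST matches lay in a peak. For CTCF, which anchors chromatin loops, the odds ratio was 63.5, and 62.9% of 13119 matches lay in peaks. RFX (36.4), NRF1 (26.4), YY1 (11.2), KLF/SP (8.60), ETS (7.33), the joint OCT4/SOX2 site (6.03), CRE (4.84) and ESRRB (4.06) followed, and the E-box (2.11), TEAD (2.06), NFY (2.05), AP1 (1.76), OCT (1.67), MYOD (1.63) and ZFX (1.61) consensus sequences were also more frequent in peaks. GATA sites were less frequent (odds ratio 0.712, adjusted Fisher exact p = 5.25e-117), as was the GATA sequence written backwards (0.726), RUNX sites slightly so (0.976, adjusted Fisher exact p = 0.0188), and HNF4 sites did not differ by the test (1.01, adjusted Fisher exact p = 0.728). In peaks more than 1 kb from any TSS, RUNX sites were more frequent (1.08, adjusted Fisher exact p = 7.70e-13), as were HNF4 sites (1.12, adjusted Fisher exact p = 0.0142), and the odds ratios of NRF1 (14.4) and YY1 (3.32) were lower than over all peaks. In replicate 2 peaks the odds ratios were 235 for REST, 87.4 for CTCF, 65.7 for NRF1, 22.2 for YY1, 15.04 for RFX, 10.01 for OCT4/SOX2 and 2.06 for ESRRB. Replicate 2 peaks held 200 RFX and 1019 ESRRB matches, against 813 and 6433 in replicate 1.

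The windows are many, so small odds ratios pass the test. As a control each consensus was written backwards, which keeps its bases but can add or remove CpG. Of these sequences, 9 of 20 were more frequent in peaks and 7 less frequent. The backward NRF1 sequence had an odds ratio of 14.3, which rests on 8 peaks and 1 control window, and the backward KLF/SP sequence 6.09. The backward ZFX (3.97) and MYOD (1.75) sequences were above ZFX and MYOD themselves, while the backward CTCF (2.08), OCT4/SOX2 (0.527) and ESRRB (0.720) sequences were far below their forward values.

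Within peaks, many matches to CTCF, NRF1, REST and RFX lay in replicate 1 footprints. Of the CTCF matches in replicate 1 peaks, 89.6% (95% interval 88.9 to 90.2) lay in a footprint, and the shares were 91.9% for NRF1, 89.0% for REST, 79.1% for RFX, 66.7% for KLF/SP, 50.2% for ESRRB, 44.4% for OCT4/SOX2 and 4.27% for GATA. In the shallower replicate 2 these shares were 25.9% for CTCF, 77.4% for NRF1, 22.4% for REST, 27% for RFX, 29.2% for KLF/SP, 14.3% for ESRRB, 23.7% for OCT4/SOX2 and 3.17% for GATA. Against other windows of the same peaks, 15 motifs were more frequent in footprints and 4, NFY, AP1, ZFX and GATA, less frequent. NFY was near 1 (0.946, adjusted Fisher exact p = 0.0439) and turned above 1 in peaks more than 1 kb from any TSS. Written backwards, the AP1 (odds ratio 0.851), NFY (0.702) and GATA (0.468) sequences were less frequent in footprints too, and that of KLF/SP was more frequent (8.01). In footprints of the stronger 50% of peaks the calls of TEAD (1.01, adjusted Fisher exact p = 0.843) and HNF4 (1.23, adjusted Fisher exact p = 0.1498) ended. Over the footprints of all replicate 1 peaks, the odds ratios were 137 for REST, 100.4 for CTCF, 76.9 for NRF1, 62.6 for RFX, 16.5 for KLF/SP, 12.8 for ESRRB and 12.6 for CRE. Those of REST, NRF1 and RFX rest on 2, 8 and 10 control windows with a match. In replicate 2 footprints the odds ratios were 6.88 for REST, 11.6 for CTCF, 13.5 for RFX, 6.99 for KLF/SP, 4.47 for ESRRB and 6.88 for CRE. There 8 control windows held a REST match, 4 an RFX match and none an NRF1 match. There 12 motifs were more and 3 less frequent, and the calls of AP1 (0.901, adjusted Fisher exact p = 0.327), GATA (0.708, 0.0885), MYOD (1.02, 0.741) and HNF4 (1.33, 0.699) ended. YY1 sites were more frequent in replicate 1 footprints (4.03, adjusted Fisher exact p = 8.57e-18) and less frequent in the fewer footprints of replicate 2 (0.464, adjusted Fisher exact p = 0.0393). The replicate 2 value rests on 13 footprints and 28 control windows with a match.

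**Figure D4:**
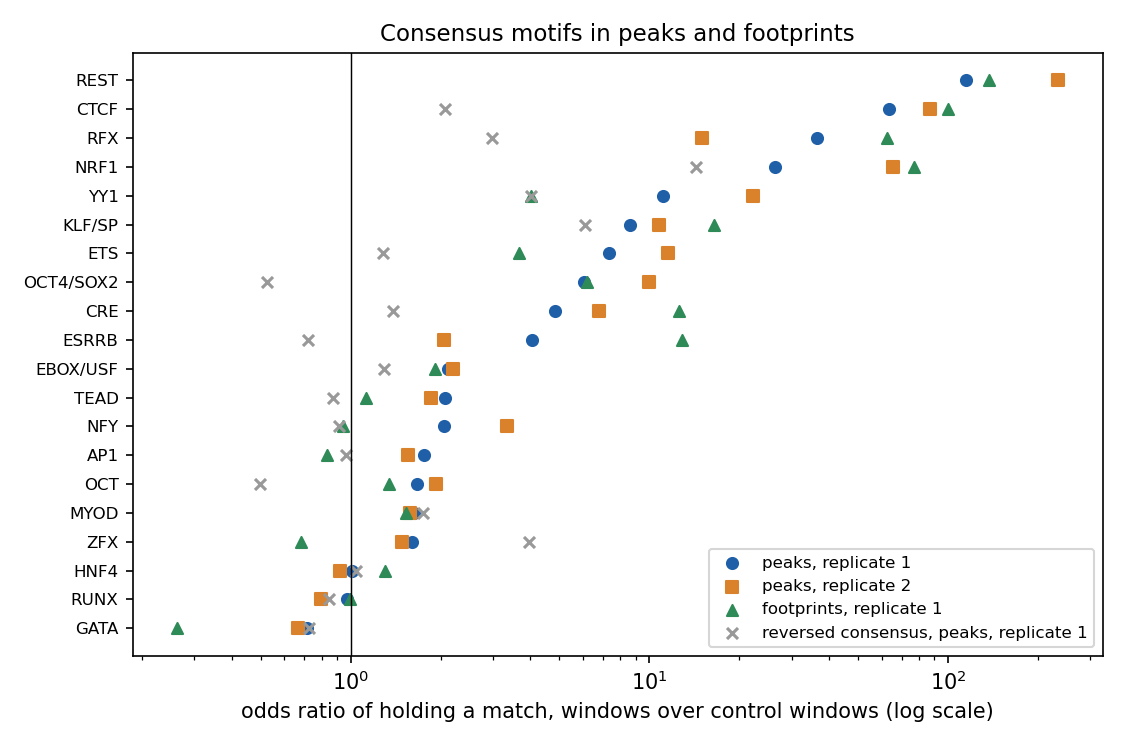
Odds ratio of holding a match to each of 20 consensus motifs (horizontal axis, log scale), for replicate 1 peaks (blue circles) and replicate 2 peaks (orange squares) against flanking windows, for replicate 1 footprints against other windows of the same peaks (green triangles), and for the consensus written backwards in replicate 1 peaks (grey crosses, REST left out because no control window held it). REST and CTCF lie farthest right, at 115 and 63.5 in replicate 1 peaks, and GATA lies left of 1.

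Promoter peaks on chromosome X were lower than those on the autosomes. Among CpG-rich promoters with a peak, the median height on X was 0.573 times that on the autosomes in replicate 1 (95% bootstrap interval 0.521 to 0.630) and 0.606 times in replicate 2 (0.525 to 0.702). The same ratio for single autosomes ran from 0.827 on chromosome 13 to 1.40 on chromosome 7 in replicate 1, and from 0.852 on chromosome 12 to 1.33 on chromosome 7 in replicate 2. Over all promoters, a peak was present at 61.8% of 948 protein-coding genes on X and at 75.0% of 20807 on the autosomes in replicate 1. Among CpG-rich promoters, 223 of 226 on X and 9445 of 9511 on the autosomes had one, and CpG-rich promoters made up 23.8% of the genes on X and 45.7% on the autosomes. This comparison was added after the data were seen.

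**Figure D5:**
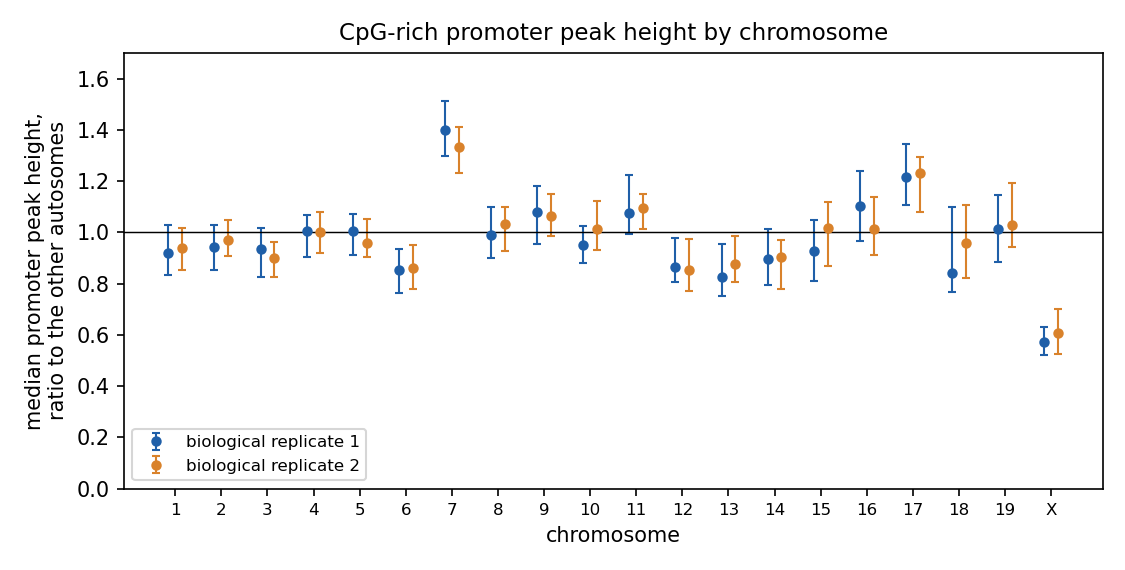
Median height of CpG-rich promoter peaks on each chromosome divided by that on the other autosomes (vertical axis, ratio), in replicate 1 (blue) and replicate 2 (orange), with 95% bootstrap intervals, for chromosomes with at least 20 such peaks. X lies lowest at 0.573 and 0.606, and chromosome 7 highest at 1.40 and 1.33.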

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

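Replicate 2 is much shallower than replicate 1, no comparison at equal depth was made, and 1 group with 2 biological replicates allows no test across samples. Of 363 values under alternatives, 281 kept their side of the threshold and the direction of any call, or stayed near the main value. Values without a call in both settings counted as kept even where their direction changed. Of the rest, 29 lost and 14 gained a call, 6 reversed and 33 moved, and the cause was not tested. The genomic distribution without replicate 1 always counted as moved, because its bound was the SD of the same 2 replicates. Overlap of replicate 1 and replicate 2 peaks was 23.9% and 77.8% with reciprocal overlap of 50%, 30.2% and 98.3% in the stronger 50% of each list, 71.6% and 71.8% with equal numbers, 27.7% and 96.3% in the stricter lists, and 27.5% and 93.5% in the 150 bp lists. Spearman's rho was 0.844 in the stronger 50% and 0.908 in the stricter lists. The intergenic share was 35.3% in the stronger 50%. Without replicate 1 the shares were 23.4% for promoters, 4.53% for exons, 34.8% for introns and 37.2% for intergenic sequence.

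Gene lists below other genes numbered 1 with promoters of 1 kb and 4 in the stronger 50%, and 5 lists were above with the 5′-most TSS. Within the CpG class 5 were above and 1 below. Without replicate 1, 4 were above and 6 below, and Hox genes (30.8% of members) turned from above to below other genes. There neural ectoderm (55.6%) lost its call with a share under that of other genes, and mesoderm (22.2%), with no call in replicate 1, was below them. For distal peaks, 2 lists were below the central range within 100 kb and 3 in the stronger 50%. With reciprocal overlap, 3.71% of replicate 1 and 30.03% of replicate 2 footprints were overlapped. In peaks more than 1 kb from any TSS, 1 motif was below control windows, RUNX in peaks turned to 1.08 and NFY in footprints to 1.14. Without replicate 1 the YY1 odds ratio in footprints turned to 0.464. For the consensus written backwards, the only alternative chosen after the data were seen, 9 motifs were above and 7 below in peaks, and 3 above and 8 below in footprints. The stronger 50% of the footprint lists by their own score could not be taken, because every footprint carries the same FDR, so footprints in the stronger 50% of peaks were used for the motifs.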

Other observations

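Further genes, chosen after the promoter lists had been read, add to the picture of the R1 genome. The promoter of Xist, the RNA that silences an X chromosome, had a low peak in replicate 1 (0.326) and none in replicate 2, as did that of Jpx (0.233). The antisense partner of Xist, Tsix, had heights of 3.70 and 4.23, Ftx 3.95 and 3.55, and Rlim, an activator of Xist, 4.92 and 4.71. On chromosome Y, peaks were present at the promoters of Eif2s3y (1.85 and 1.39), Uty (2.61 and 1.94) and Ddx3y (2.63 and 1.42) in both replicates. Usp9y had low peaks (0.133 and 0.192), and Kdm5d had a low peak in replicate 1 alone (0.195). None was called at Sry, the testis-determining gene, or Zfy1. At the annotated start of Mir302b, of a microRNA cluster active in pluripotent cells, the heights were 7.56 and 3.31. At that of Mir290a, of another such cluster, the height was 1.71 in replicate 1, with no peak in replicate 2. Both annotations cover only a short stretch (chr3:127545228–127545301 and chr7:3218626–3218708), so these windows need not hold the promoters of the clusters. Among other non-coding RNA genes, Tug1 had 10.7 and 8.38, Gas5 8.20 and 6.07, Neat1 6.94 and 4.75 and Malat1 4.17 and 3.48. Of the DNA methylation and Polycomb genes, Tet1 had 9.86 and 5.45, Suz12 7.94 and 5.50, Ezh2 6.44 and 5.45 and Dnmt3l 4.80 and 3.82, while Dnmt3b, a gene of primed cells, had 0.955 in replicate 1 and no peak in replicate 2.

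The tallest peak of replicate 1, at chrX:143483001–143483160, 35510 bp from the nearest protein-coding TSS, that of Pak3, had a height of 128, which is 356 times the median of the list. No peak of the main or stricter replicate 2 list overlapped it, but a 150 bp peak and a hotspot of replicate 2 did. Of its 31-base words, 28.5% occurred elsewhere in mm10.

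The 3 patterns below were noticed in the data, and all tests on them were chosen after the main results were seen. Except for the share of sequence with further copies, each was set down before its own result was seen. No biological difference between samples was tested, because they form a single group. The number of X chromosomes is a property of the line that the labels do not give.

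Hox promoters had a peak in 39 of 39 cases in replicate 1 and in 12 in replicate 2. Other promoters with the same replicate 1 height gave 24.96 on average (central 95% from 20 to 30), so the observed 12 counts against the lower depth of replicate 2 as the whole cause. Wide regions of raised cutting that hide single peaks might also lower the number, yet for the 38 Hox promoters in a hotspot, promoters matched on height and on hotspot width gave 24.04 (19 to 29) against 12, spread over all 4 clusters (5 at Hoxa, 2 at Hoxb, 2 at Hoxc and 3 at Hoxd). Neural ectoderm (10 against 14.2), mesoderm (4 against 8.48) and signalling genes (16 against 18.2) also fell below their height-matched range, while 14 lists lay inside theirs, among them endoderm (8 against 6.93), trophoblast (8 against 7.75) and primed pluripotency genes (8 against 8.35). The cause stays open, since genes of a cluster are not independent and only 2 biological replicates were compared.

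CpG-rich promoter peaks on X were 0.573 times as high as on the autosomes in replicate 1 (0.521 to 0.630). This ratio is the pattern itself and adds nothing for a single X chromosome per cell, which was therefore tested away from promoters, at distal peaks with a CTCF match. There the ratio was 0.379 (0.324 to 0.449) in replicate 1 and 0.447 (0.404 to 0.511) in replicate 2, under the bound of 0.6 set beforehand and under every autosome tested (lowest 0.843 and 0.851), though in replicate 1 also under the 50% that copy number alone could give. Fewer CpG-rich promoters on X (23.8% of genes against 45.7%) are unlikely to be the cause, because among CpG-rich promoters alone the replicate 2 ratio was 0.606 (0.525 to 0.702). That the cells carry 1 X is a hypothesis, which goes with the peaks at Y-linked promoters, and lower activity of the X as a further cause stays open.

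The 5055 replicate 2 peaks without a replicate 1 peak were low, with a median height of 0.456 against 1.06 for the others. Of them, 64.8% (63.5 to 66.1) held a base with FDR up to 0.05 in replicate 1, which is consistent with enriched cutting there that was not called as a peak at that place. Calls near the threshold may account for many, as their odds of being in the stricter list were 0.141 times those of the overlapped peaks (0.132 to 0.151). Among the 4075 of them that were scored, sequence with further copies in the genome was 1.87 times as frequent (1.37 to 2.55) as in 4075 overlapped peaks, at 2.75% (2.27 to 3.30) against 1.47%, so it cannot account for most of them. The tallest of them lay at chr8:20424781–20424834 (23.3, 61.6 kb from Gm15319, not scored) and chrX:169998241–169998400 (10.3, with 100% of its words elsewhere in mm10).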
